A study of Mus musculus with 12 samples.

How the data were processed

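Transcript levels were measured in 12 samples of sorted mouse tumour macrophages, 6 labelled YFP+ and 6 labelled YFP−. Per the labels' protocols, animals were implanted with tumours, cells were sorted into lysis buffer, and total RNA was amplified as cDNA, chemically labelled with Cy5 and hybridised to Agilent mouse arrays. The scanner files used here are of the 4x44K design and hold only the red channel. The deposited intensity values, per the file headers, come from Agilent Feature Extraction 11.5.1.1 (also in the submitters' processing notes), whose processed signal has the background subtracted and spatial trends within the array removed, with no scaling between arrays. The authors also deposited a value table, per its values on a log2 scale: each of its 12 columns had a median of 8.83 and a Spearman rank correlation of 1 with the log2 processed signal of its array, so its scale and direction match the scanner values. Medians and 75th percentiles were equal across its columns, as after quantile normalization, and its genes were not centred. It served as an alternative. The number of its columns not used was 0.

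The red processed signal took the place of the green one usual for one-colour arrays. Control spots (1377) and spots with outlier flags in the deposited files were left out, the spots of each of 399 probes printed 10 times were averaged, and 35 of 39429 probes had no value on some array and were left out. No probe was saturated. Signals were put on a log2 scale, and each array's 75th percentile was subtracted. Probes well above background on at least 6 of the 12 arrays were kept (25434), and each gene was represented by its probe with the highest mean, which gave 20370 genes and features. Of these, 4165 had several passing probes, and in 1609 at least 1 of those differed in direction from the probe used. Accessions of 28330 probes matched a RefSeq gene table, used for names alone, which changed 1403 names, and 11099 probes kept the array's name. Of the tested features 5400 are named only by an accession, clone or interval. Positions are those of the array annotation in mm9 per the file headers, and no genome sequence was used here.

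Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only factor, all 12 arrays), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors given with a gene's fold are limma's moderated standard errors on the log2 scale. For 26 gene lists, camera was run with a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data, beside fry, which tests whether a list's genes move one way and does not compare them with other genes. Lists with fewer than 5 tested genes would have been left out; there were 0. A list's score is the mean over its genes of the centred log2 signal, compared by an exact two-sided permutation test. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0 were also used.

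The groups, tests, lists, the rule for named genes and the other settings to try were fixed before the data were examined. The rule took, among called genes with the same sign in all 6 tumour numbers, the 10 largest differences in each direction, passing over features named only by an accession, clone or interval. It added up to 4 members of each list with the smallest p, and 10 genes named in advance, of which 9 were tested. Ly6c2 was not among the names found in the annotation and was not analysed here. Names of the Gm series were admitted as gene names. The immunoglobulin chain family, taken from the array's descriptions by search words, was chosen after the values were seen.

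The test for genes was checked on simulated data over the same 20370 genes: of 100 genes changed by 1 on the log2 scale 23 were called (mean estimate 1.02), of 100 changed by 2 on that scale 66 were called (2.03), and of 20145 unchanged genes 10 were called. A simulated list shifted by 1 was called, and 0 of 25 unchanged lists. The simulated genes vary independently, so this gives no rate for the real arrays, where 91 of 99 other divisions of the samples called 1 or more lists (median 6). Many of those divisions keep part of the real difference between the groups. The other settings fixed in advance were the tumour number as a block, fixed or random, slide as a block, both together, normexp background correction with an offset of 50, quantile normalization, the deposited table, median centring, no filter or a filter on all 12 arrays, the mean of a gene's probes, every probe alone, an intensity trend with robust variances, array weights, other thresholds, the estimated correlation, fry, lists without shared members, and leaving out each array or each pair. Array brightness as a covariate, leaving out slide 3, and each slide alone were added after the data were seen. Macrophages of normal pancreas and of other mice named in the series' design text were not analysed here.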

Results

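Gene expression was measured on 12 one-colour Agilent mouse arrays, each hybridised with amplified, Cy5-labelled cDNA from macrophages sorted out of mouse pancreatic tumours. The labels divide the samples into 6 YFP+ and 6 YFP− macrophage samples, and 6 tumour numbers occur once in each group. The series' design text names mice that combine an Flt3-driven Cre recombinase with a YFP reporter behind a stop cassette. Flt3 is a receptor of haematopoietic progenitors, so in such mice YFP marks cells that descend from a progenitor that expressed Cre. That text also names wild-type and KPC mice, and the genotype of these 12 samples is not provided, so that YFP has this meaning here is taken from the design text alone. The comparison is between tumour macrophages labelled YFP+ and YFP−. The arrays lay on 3 slides, each with 2 YFP+ and 2 YFP− arrays. The labels do not say whether equal tumour numbers mean the same animal or whether different numbers are separate animals, so p-values measure only the spread between these samples, which may be partly technical.

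YFP+ arrays were brighter. Their 75th percentile of processed signal was 3643 ± 280 (SD, n = 6 arrays) against 2631 ± 427 (SD, n = 6) in YFP− (two-sided exact permutation p = 0.0043, higher in 6 of 6 tumour numbers). The share of spots well above background was 64.9% ± 0.92 in YFP+ and 63.4% ± 1.18 in YFP− (SD, n = 6 each, two-sided exact permutation p = 0.030, higher in 5 of 6). Each array was scaled to its own 75th percentile before testing. The number of arrays limits the precision of every value given here.

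Of 20370 genes and transcript features tested with limma, 356 differed at an adjusted p under 0.05, and 2288 had an unadjusted p under that value. YFP− macrophage samples were higher for 288 features, with a median difference of 6.84-fold, and YFP+ samples for 68, with a median of 18.3-fold. The difference had the same sign in all 6 tumour numbers for 274 of the 288 and 65 of the 68, which is no separate support, since the features were selected on the same arrays. With slide as a block, 433 features were higher in YFP− and 123 in YFP+. These included 271 of the 288 and 65 of the 68, and all 356 differences, so selected, had the same sign within each of the 3 slides. With the tumour number as a block, 246 features were higher in YFP− and 50 in YFP+, among them 196 of the 288 and 38 of the 68. Within a single slide, with 2 arrays against 2, limma called 0 features on each, with 1848, 1796 and 1617 features at an unadjusted p under 0.05. With array brightness as a covariate, a fit added after the data were seen, 13 features passed, 9 higher in YFP− and 4 in YFP+. All 356 differences kept their sign in that fit, again no separate support, since they were selected on the same arrays. Their median size was 2.71 against 2.94 on the log2 scale. The median standard error rose from 0.48 to 0.83, since brightness and group were correlated (Pearson r = 0.825 over 12 arrays). When each array was centred on its median in place of its 75th percentile, 33.5% of the called features were higher in YFP+, against 19.1%, and the median difference of all genes moved to 0.18 on the log2 scale.

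The largest differences toward YFP− included genes known from epithelium and connective tissue. Gcnt3, a glycosyltransferase of mucin synthesis, was 57.4-fold higher in YFP− (log2 difference −5.84, SE 0.69, n = 6 per group, limma adjusted p = 9.0e-04). Mal, a membrane proteolipid of polarised epithelia, was 43.7-fold higher (−5.45, SE 0.66, adjusted p = 0.0010). F2rl1, a protease-activated receptor, was 27.8-fold higher and Igsf5, a junctional adhesion molecule, 28.2-fold. Sparcl1, a secreted matrix-associated glycoprotein, was not well above background on any of the 6 YFP+ arrays and was at least 9.04-fold higher in YFP− (adjusted p = 7.9e-04). The other genes with the largest differences in this direction were Gm3776, Eml1, Ms4a4d, Gm10639 and Cdr2l, 26.6-fold to 57.1-fold higher in YFP−. The other 9 besides Sparcl1 were well above background on only 1 to 3 of the 6 YFP+ arrays, so their folds rest partly on dim spots. For the fold of a gene not above background in a group, the dim group's mean uses, on each array, the higher of the gene's own signal and the lowest signal well above background.

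Collagen and structural matrix genes were lower in YFP+ for every one of the 27 tested. Over all genes tested 17 fell in YFP+, and 22 fell adjusted over the list alone. The median log2 difference was −1.90, and −1.44, −2.11 and −2.56 within the 3 slides. Bgn, the small proteoglycan biglycan, fell 5.40-fold (log2 −2.43, SE 0.24, n = 6 per group, limma adjusted p = 3.2e-04), with its probe on chromosome X from 70738554 to 70738613 in build mm9 per the file headers. The basement membrane gene Nid1 fell 5.68-fold (SE 0.24), Col18a1 11.2-fold (SE 0.49) and Col6a1 5.73-fold (SE 0.36), each in 6 of 6 tumour numbers. The list passed camera (adjusted p = 2.0e-26, and 1.6e-21 with slide as a block) and held with an estimated correlation (adjusted p = 0.014).

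Fibroblast markers moved the same way. Of 16 tested, 7 fell in YFP+ and 0 rose, and 12 fell adjusted over the list alone, with a median log2 difference of −1.73 and within-slide medians of −1.39, −1.91 and −1.95. Mfap5, a microfibril-associated glycoprotein, fell 6.01-fold (SE 0.29 on the log2 scale) and Postn, the matricellular protein periostin, 5.79-fold (SE 0.33). The fibrillar collagen genes Col3a1 and Col1a1, which are also in the matrix list, fell 3.30-fold and 3.22-fold. The list passed camera (adjusted p = 5.1e-13, 8.6e-12 with slide as a block, and 0.023 with an estimated correlation), with a lower score in YFP+ in 6 of 6 tumour numbers.

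Tumour and ductal epithelial markers were lower in YFP+ for all 19 tested. Over all genes tested 9 fell, and 15 fell adjusted over the list alone. The simple-epithelium keratins Krt19, Krt8 and Krt18 fell 7.68-fold (SE 0.47), 6.01-fold (SE 0.33) and 4.32-fold (SE 0.33), and the epithelial mucin Muc1 fell 4.95-fold (SE 0.31), each in 6 of 6 tumour numbers. The median log2 difference was −2.31 (within slides −2.23, −1.83 and −2.60), with a camera adjusted p of 1.9e-20, 8.7e-18 with slide as a block and 0.018 with an estimated correlation. Markers of other cells in the tissue moved with these groups. All 8 red cell genes were lower in YFP+ (median −2.10; within slides −1.90, −1.78 and −2.38; camera adjusted p = 1.5e-07, 1.2e-05 with slide as a block), 5 of them called and 6 adjusted over the list alone, including the globin genes Hbb-b1 (12.5-fold) and Hbb-b2 (5.22-fold). That call was lost with an estimated correlation (adjusted p = 0.088). All 19 acinar genes were lower in YFP+ too (median −1.69, camera adjusted p = 1.1e-07, 1.3e-05 with slide as a block), but only Cela1, a pancreatic elastase, was called, over all genes and adjusted over the list alone. The acinar medians were −0.67, −0.49 and −4.27 within slides, the call was lost without slide 3 (adjusted p = 0.19), and the adjusted p was 0.31 with an estimated correlation.

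**Figure D1:**
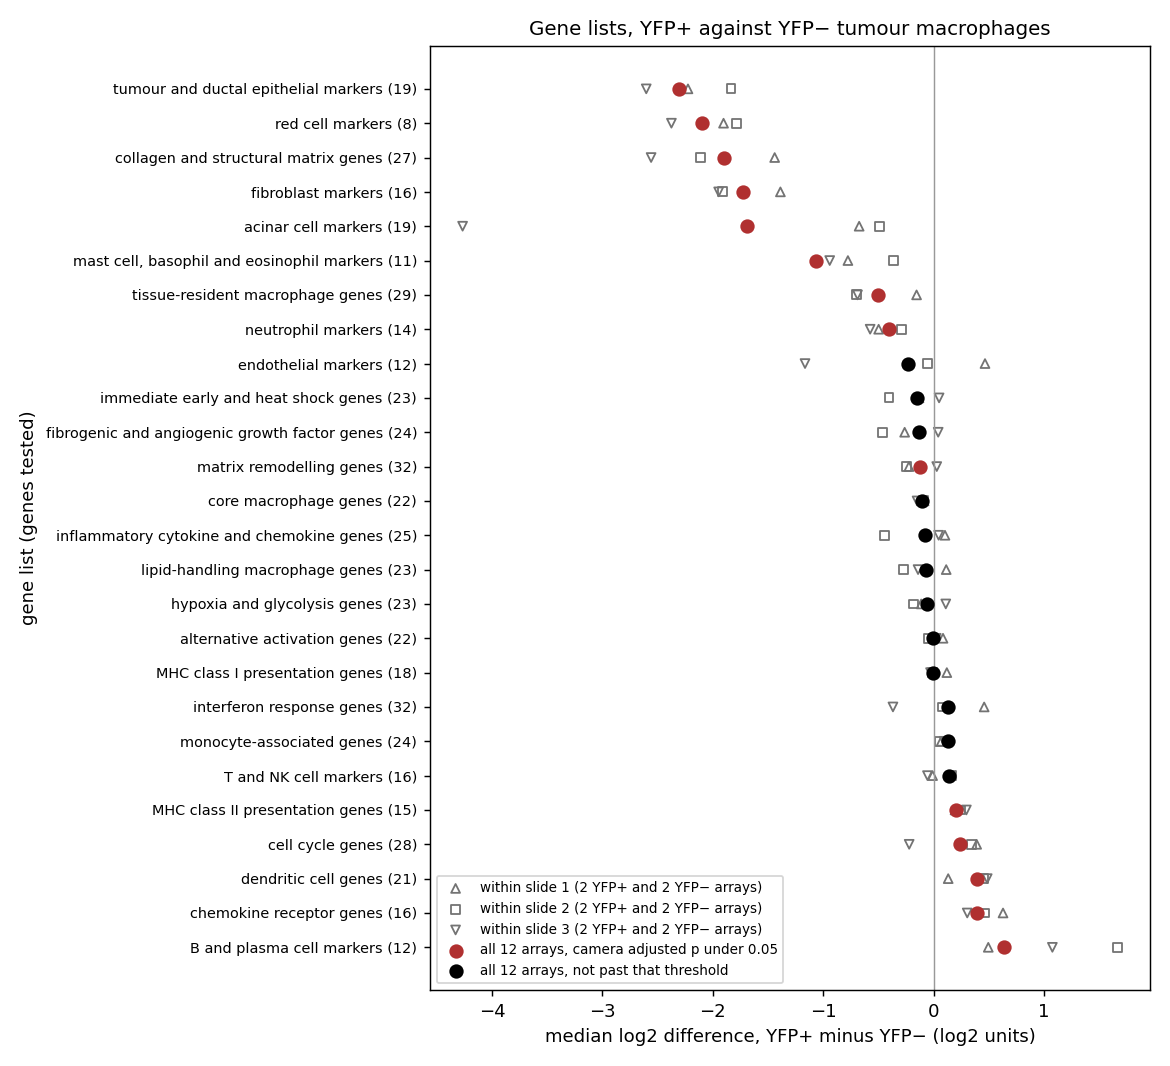
Median log2 difference (YFP+ minus YFP−, log2 units, horizontal axis) of each of the 26 gene lists, with the number of genes tested in brackets. Filled points are all 12 arrays, red where camera's adjusted p was under 0.05, and open symbols are the medians within each slide. Epithelial (−2.31), red cell (−2.10), matrix (−1.90) and fibroblast (−1.73) lists lie far to the left on every slide, and the acinar list does so mainly on slide 3 (−4.27).

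Granulocyte markers were lower in YFP+ as well. Of 11 mast cell, basophil and eosinophil genes 3 fell in YFP+, and 4 adjusted over the list alone: the basophil protease Mcpt8 fell 13.9-fold (SE 0.61), the interleukin-5 receptor subunit Il5ra 7.86-fold (SE 0.51) and the mast cell tryptase Tpsb2 2.38-fold (SE 0.24). The median was −1.07 (camera adjusted p = 0.013, 0.040 with slide as a block, 0.10 with an estimated correlation). Within slides it was −0.78, −0.36 and −0.94, and with only probes above background on all arrays it was 0.04. With 1 array left out the median ranged from −1.32 to −0.21, and the call was lost without the YFP− array of tumour 1 (adjusted p = 0.055). None of the 14 neutrophil genes was called over all genes by limma, and adjusted over the list alone 4 fell and 1 rose. S100a9 and Ltf, abundant granule or cytosolic proteins of neutrophils, had log2 differences of −1.67 (SE 0.42) and −1.65 (SE 0.41), both negative in 6 of 6 tumour numbers. In all 10 members had negative and 4 positive differences, and the chemokine receptor Cxcr2 went the other way (1.02, limma adjusted p = 0.15). The neutrophil median was −0.40 (camera adjusted p = 0.021, 0.040 with slide as a block, 0.27 with an estimated correlation), with −0.50, −0.29 and −0.57 within slides, and the call was lost without the YFP− array of tumour 6 (adjusted p = 0.11) or the YFP+ array of tumour 4 (0.070).

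Matrix remodelling genes had a lower mean score in YFP+ in 6 of 6 tumour numbers (two-sided exact permutation p = 0.0022, fry adjusted p = 0.037), but the members did not all share that direction. Of 32 tested, 4 fell in YFP+ (7 adjusted over the list alone): the collagen cross-linking enzyme Lox 8.17-fold (SE 0.47), the metalloproteinase inhibitor Timp3 6.05-fold (SE 0.53), the stromelysin Mmp3 10.3-fold (SE 0.74) and the aggrecanase Adamts4 11.1-fold (SE 0.76). With 1 array left out, the calls of Timp3, Mmp3 and Adamts4 were kept in 4, 1 and 2 of 12 fits. Another 12 members had positive differences, and the median was −0.12, positive with median centring (0.09) and within slide 3 (0.03). The camera adjusted p was 0.030, with 0.053 when slide was a block and 0.27 with an estimated correlation, and the call was kept in 5 of 12 fits with 1 array left out. Among the growth factor genes the matricellular signalling genes Ccn2 and Ccn1 fell 14.8-fold (SE 0.57) and 8.55-fold (SE 0.46), while that list of 24 did not pass camera (median −0.13, adjusted p = 0.12, 3 fallen adjusted over the list alone). Its mean score was lower in YFP+ in 6 of 6 tumour numbers (two-sided exact permutation p = 0.0022, fry adjusted p = 0.086). The fibroblast and epithelial markers above were lower in the same YFP+ samples.

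Tissue-resident macrophage genes were lower in YFP+ by a smaller amount. Of 29 tested, 27 had negative differences, with a median of −0.50 (1.42-fold), and the list score was lower in YFP+ in 6 of 6 tumour numbers (two-sided exact permutation p = 0.0022). No member was called over all genes by limma, and 4 fell adjusted over the list alone. Timd4, a phosphatidylserine receptor of long-lived resident macrophages, had the largest of these (log2 −2.16, SE 0.51, n = 6 per group, adjusted p = 0.056, negative in 6 of 6). The complement receptor Vsig4 was at −1.78 (SE 0.45, adjusted p = 0.083), the iron exporter Slc40a1 at −1.55 (SE 0.45, 0.13) and the selenium carrier Selenop at −0.65 (SE 0.18, 0.11). The list passed camera (adjusted p = 4.6e-07, and 7.2e-06 with slide as a block), with medians of −0.15, −0.70 and −0.69 within slides. With an estimated correlation the adjusted p was 0.10. Epithelial markers, with a median of −2.31, and fibroblast markers, with −1.73, were lower in the same samples.

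The genes that define macrophages as a class showed no called shift as a list. The 22 core macrophage genes had a median of −0.11 (camera adjusted p = 0.61, 0 called by limma over all genes or over the list alone). Of these 17 were negative and 5 positive. The 24 monocyte-associated genes had a median of 0.13 (adjusted p = 0.65), with 17 positive and 7 negative. Among the monocyte-associated genes the calcium-binding protein S100a6 fell 2.12-fold (SE 0.20), the single call over all genes and over the list alone. Ly6c1 (−1.33) and Plac8 (−1.05) were also negative and not called (limma adjusted p = 0.27 and 0.16). The colony-stimulating factor receptor Csf1r differed by −0.16 (SE 0.29, adjusted p = 0.91) and the F4/80 gene Adgre1 by −0.19 (SE 0.23, 0.85). Flt3 itself differed by 0.64 (SE 0.35, adjusted p = 0.55), positive in 6 of 6 tumour numbers, and the monocyte chemokine receptor Ccr2 by 0.30 (SE 0.21, 0.66), also positive in 6 of 6. Cx3cr1 differed by 0.04 (SE 0.32), Cxcr4 by −0.22 (SE 0.19), the mannose receptor Mrc1 by −0.42 (SE 0.19), and the class II genes H2-Aa and Cd74 by −0.19 (SE 0.27) and −0.21 (SE 0.23), with adjusted p from 0.44 for Mrc1 to 0.98 for Cx3cr1. None of these 9 genes passed the threshold.

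**Figure D2:**
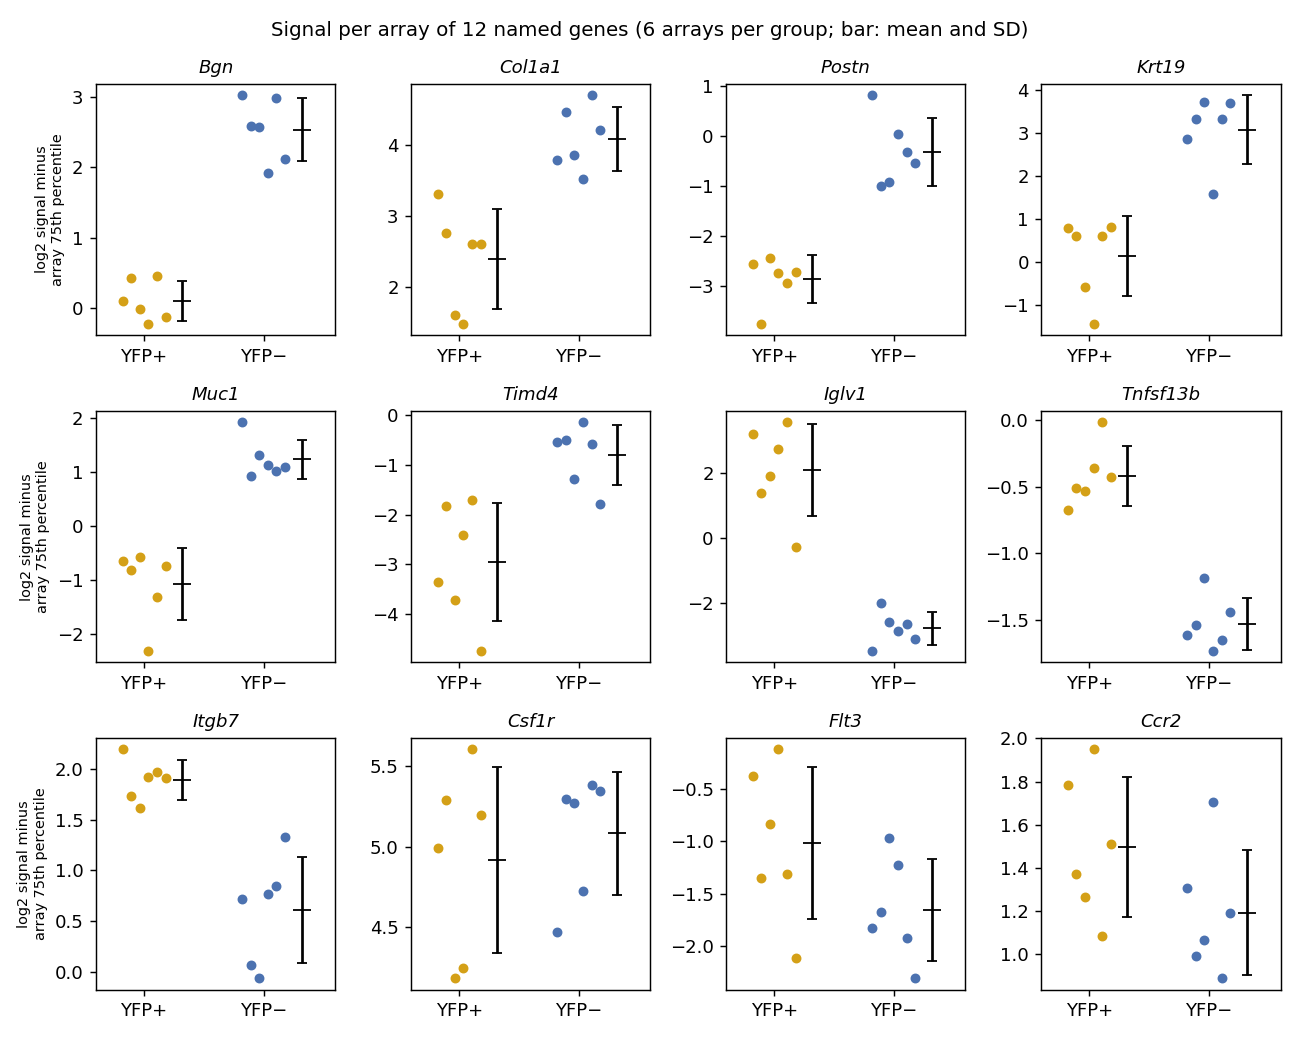
Signal of 12 named genes on each array (log2 of processed signal minus the array's 75th percentile, vertical axis), YFP+ in yellow and YFP− in blue, with bars for the mean and SD of 6 arrays. Bgn, Postn and Muc1 do not overlap between groups and are higher in YFP−, Iglv1 and Tnfsf13b do not overlap and are higher in YFP+, and Csf1r, Flt3 and Ccr2 overlap.

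Immunoglobulin chain transcripts made up most of what was higher in YFP+. Of 139 tested features that the array annotation describes as immunoglobulin chains, 44 rose in YFP+, by 5.57-fold to 375-fold, and 0 fell over all genes by limma. Among the other described features 16 rose, an odds ratio of 504 (95% interval 267 to 1006, Fisher's exact p = 1.8e-82) over the 17678 described features, which are not independent because chain genes are near copies of each other. The median of the 139 was 3.77 on the log2 scale (13.7-fold), with 134 of 139 positive, and 2.18, 4.24 and 4.93 within slides. Folds given for the family as a whole carry no background bound, so they may rest partly on dim YFP− spots. Of all 68 features higher in YFP+, 5 were not well above background on any YFP− array. The mean score was higher in YFP+ in 6 of 6 tumour numbers (two-sided exact permutation p = 0.0022), and 66 rose with slide as a block. This family was chosen after the values were seen. By the array's mm9 positions 22 of the 44 lie on chromosome 12, 19 on chromosome 6 and 2 on chromosome 16. Iglv1, a lambda light chain variable gene whose probe lies on chromosome 16 from 19061905 to 19061964, rose 29.5-fold (log2 4.88, SE 0.57, n = 6 per group, adjusted p = 8.0e-04).

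Genes outside that family rose in YFP+ too. Tnfsf13b, the B cell survival factor BAFF, rose 2.16-fold (SE 0.17, limma adjusted p = 0.0053), Itgb7, a mucosal homing integrin subunit, 2.43-fold (SE 0.24, 0.019) and Ltb4r1, the leukotriene B4 receptor, 2.70-fold (SE 0.30, 0.032). The retinol dehydrogenase Dhrs9 rose 3.50-fold (SE 0.31) and the nucleolar protein gene Lyar 2.21-fold (SE 0.25). Slc8a2, a sodium-calcium exchanger, was not well above background on any YFP− array and was at least 3.04-fold higher in YFP+ (adjusted p = 5.8e-04). Zmat5 rose 9.44-fold (SE 0.51) and was above background on 2 of 6 YFP− arrays. Gm6460 and Strc rose 3.35-fold and 2.95-fold. All 10 genes, Iglv1 included, passed with slide as a block. With 1 array left out, the calls of Ltb4r1, Lyar and Strc were kept in 4, 2 and 2 of 12 fits.

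By camera, 5 gene lists were higher in YFP+, and none of these calls held with an estimated correlation. Camera with the preset correlation also called a median of 6 lists in 99 other divisions of the 12 arrays, many of which keep part of the real difference. Dendritic cell genes had a median of 0.39 over 21 genes (adjusted p = 0.0013, 0.0014 with slide as a block, 0.27 with an estimated correlation), with 0 called by limma over all genes or over the list alone and a positive score in 6 of 6 tumour numbers. The transcription factor Irf4 differed by 0.85 (SE 0.27) and Wdfy4, which acts in cross-presentation, by 0.71 (SE 0.26). Chemokine receptor genes had a median of 0.39 over 16 genes (adjusted p = 0.0053, 0.0065 with slide as a block, 0.088 with an estimated correlation), with 0 called by limma over all genes. Adjusted over the list alone 2 rose, and Cxcr6 and Cxcr2 had the smallest p, with differences of 2.64 (SE 0.77) and 1.02 (SE 0.30). Within slides the medians were 0.13, 0.45 and 0.49 for dendritic cell genes and 0.63, 0.46 and 0.30 for chemokine receptors.

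Of the B and plasma cell markers, 12 were tested, with a median of 0.63 (camera adjusted p = 0.021, 0.0065 with slide as a block, 0.27 with an estimated correlation) and within-slide medians of 0.49, 1.67 and 1.07. Ebf1, an early B cell transcription factor also used in stromal cells, fell 11.1-fold in YFP+ (SE 0.59), against the list's direction. Jchain, which joins antibody units in plasma cells, differed by 4.78 (SE 1.47, adjusted p = 0.17 over all genes, 0.022 with slide as a block), positive in 6 of 6. Pou2af1, a transcriptional coactivator of B lineage cells, differed by 3.08 (SE 1.12, adjusted p = 0.28, 0.0049 with slide as a block), positive in 5 of 6. Adjusted over the list alone 2 rose and 1 fell. MHC class II presentation genes had a median of 0.20 over 15 genes (adjusted p = 0.043, 0.070 with slide as a block, 0.63 with an estimated correlation), with medians of 0.19, 0.25 and 0.30 within slides. Cell cycle genes had one of 0.24 over 28 genes (0.013, 0.0065 with slide as a block, 0.63 with an estimated correlation), with 0.39, 0.34 and −0.22 within slides. In both lists 0 genes were called by limma over all genes or over the list alone. The class II, cell cycle and B and plasma cell calls were each lost when single arrays were left out, among them the YFP+ array of tumour 1 (adjusted p = 0.12, 0.074 and 0.055). Without the YFP− array of tumour 6 the adjusted p was 0.30 for class II and 0.26 for cell cycle genes. The class II median ranged from 0.04 to 0.33 with 1 array left out, and was 0.71 with the brightness covariate (camera adjusted p = 1.1e-04).

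**Figure D3:**
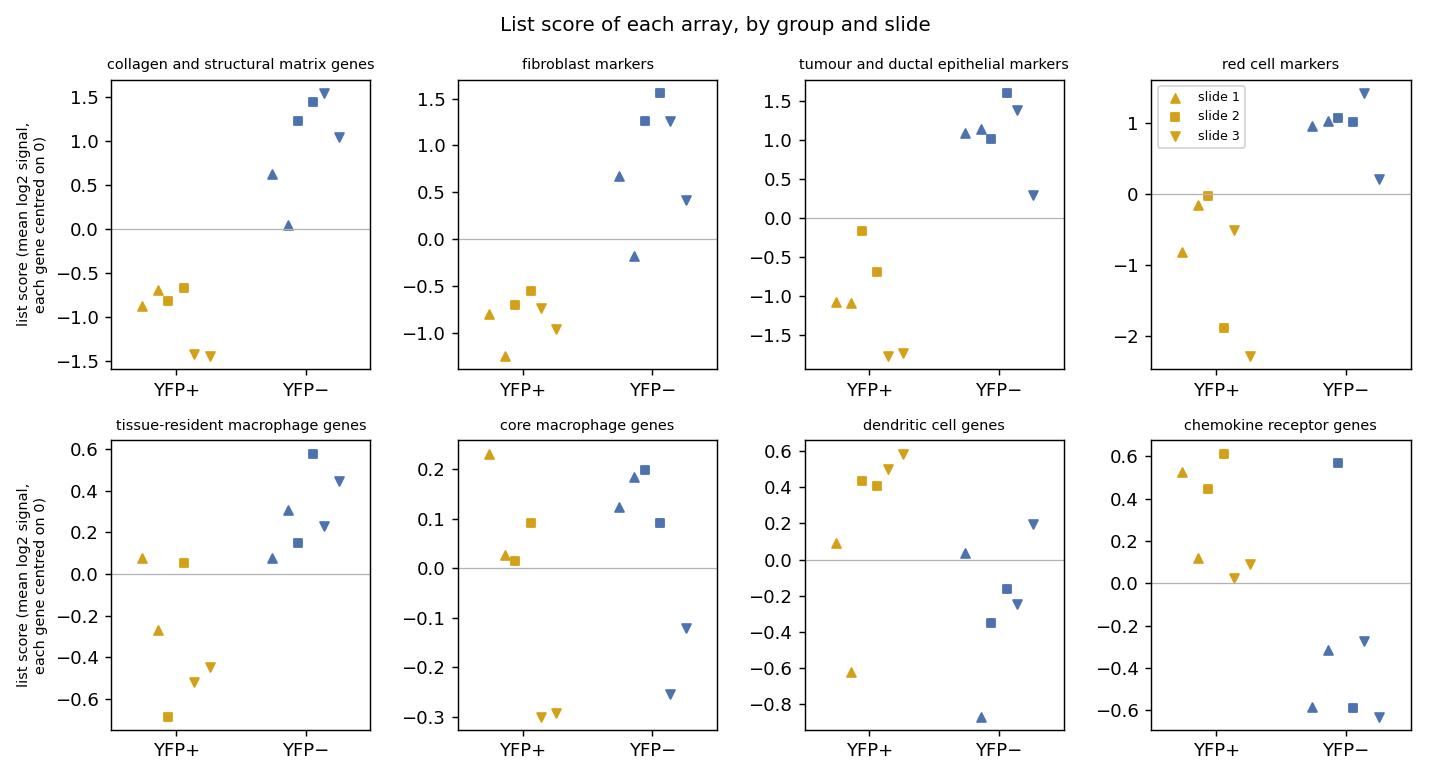
List score of each array (mean log2 signal of a list's genes, each gene centred on 0, vertical axis) for 8 lists, YFP+ in yellow and YFP− in blue, with a symbol for each slide. The matrix, epithelial and red cell scores of the 6 YFP+ arrays lie below those of the 6 YFP− arrays, and core macrophage scores overlap.

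The 12 lists that did not pass camera had medians between −0.23 and 0.14 and adjusted p from 0.12 to 0.99. Apart from the core, monocyte and growth factor lists already given, they were inflammatory cytokines and chemokines, alternative activation, interferon response, MHC class I presentation, lipid handling, hypoxia and glycolysis, immediate early and heat shock genes, and endothelial and T and NK cell markers. Within them limma called 4 genes over all genes, all lower in YFP+: S100a6, Ccn2, Ccn1 and the neutrophil chemokine Cxcl5, which fell 9.84-fold (SE 0.68) and was the only member of the inflammatory list to pass adjusted over the list alone. Alternative activation genes had a median of −0.01 over 22 genes (adjusted p = 0.78) and interferon response genes one of 0.13 over 32 (adjusted p = 0.58). The median, mean and test differed in sign for the MHC class I, alternative activation and hypoxia lists, each with a median between −0.06 and 0.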

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

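The tests of B cell markers and of fibroblast list members that are not matrix proteins, of macrophage-restricted genes and of other divisions of the samples by gene count were chosen after the results they bear on had been seen, and the brightness tests after the gene count with that covariate had been seen, those of brightness as the whole cause after their intervals too. The tests of fibroblast and epithelial markers outside every list were added after the lists' own values had been seen. Beyond those, the readings of the plasma cell and B cell tests were changed after their values were seen, as described below.

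Matrix, fibroblast and epithelial genes were higher in YFP−. With brightness as a covariate the coefficient was −1.92 (95% interval −2.91 to −0.92) against −1.94 without it, and all 3 lists passed camera in that fit. The interval excludes 0, which goes against the lower brightness of the YFP− arrays as the whole cause, but this bound was set after it was seen. Brightness and group were correlated (Pearson r = 0.825), so the fit separates them poorly. The covariate had an unadjusted p under 0.05 in 4451 of 20370 genes (0 at an adjusted p under 0.05). Brightness as 0.5 or more of the difference cannot be told apart from the group, since the interval reaches below 0.5 of −1.94. RNA of fibroblasts or tumour epithelial cells in the YFP− samples could be a source, but the tests did not decide. The lists that define the pattern cannot test it, so markers outside every list, fixed before their values were seen, were used. The 11 fibroblast markers had a median of −0.41 (exact permutation p = 0.017, 95% interval of the score difference −0.98 to −0.13), with Prrx1 called (−3.45). The 17 epithelial markers had a median of −0.79 (exact permutation p = 0.0022, 95% interval of the score difference −1.68 to −0.74), with Dsp, which was not well above background on any YFP+ array, among those called. Both sets moved toward YFP−, and neither median reached the −1 set in advance. Of these, 7 of 11 and 8 of 17 were well above background on all arrays of both groups, a baseline that could hide a small share. The remaining epithelial markers ran from −4.53 (Dsp), −3.51 (Krt23), −3.085 (Itgb4) and −3.00 (Cgn) up to 1.66 (Ildr1), with Dsp alone called. The remaining fibroblast markers ran from −3.45 (Prrx1) to 0.36 (Twist1), with Prrx1 alone called. Low signal in YFP+ by itself selects markers that fall, so these decide nothing. Within the fibroblast list, the 9 members that are neither in the matrix list nor matrix proteins had a median of −1.61 (exact permutation p = 0.017), with 0 called by limma and 5 at an unadjusted p under 0.05, and Pdpn (−0.27), Fap (−0.45) and Gsn (0.27) moved little. A matrix programme of YFP− macrophages was not tested and stays open, although such a programme does not hold the epithelial markers. The labels describe sorted macrophages.

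Immunoglobulin chain transcripts were higher in YFP+. With brightness as a covariate the coefficient was 4.75 (95% interval 1.71 to 7.78) against 3.72 without it. The interval excludes 0, which goes against the lower brightness of the YFP− arrays as the whole cause, again by a bound set after it was seen. As 0.5 or more of the difference, brightness cannot be told apart from the group, because the interval reaches below 0.5 of 3.72. RNA of plasma cells could be the source: 12 plasma cell markers had a median of 0.16 (exact permutation p = 0.23, 95% interval of the score difference −0.18 to 0.69), which met the bound set in advance against this explanation, but that bound was wrong because 11 of the 12 were well above background on all 6 YFP− arrays, a baseline that would hide a small share of plasma cells, and this objection was raised after the value was seen. Tnfrsf17, the 1 marker with a low baseline, had a difference of 1.81 (SE 0.999, adjusted p = 0.56) and Jchain one of 4.78 (adjusted p = 0.17), neither called. Tnfrsf17 was well above background on 6 of 6 YFP+ and 2 of 6 YFP− arrays. With slide as a block Jchain (adjusted p = 0.022) and Pou2af1 (3.08, adjusted p = 0.0049) passed, which goes with RNA of B lineage cells, and Tnfrsf17 did not (adjusted p = 0.070). Creld2 (2.01-fold, adjusted p = 0.036) passed too, but it was well above background on all 6 YFP− arrays and so decides nothing. Sdc1 (−1.13, higher in YFP+ in 0 of 6 tumour numbers, adjusted p = 0.084 with slide as a block) and Fkbp11 (−0.91, 1 of 6) were lower in YFP+. They too were well above background on all 6 YFP− arrays and so decide nothing. Since the baseline leaves these markers undecided, plasma cell RNA and another origin cannot be told apart. RNA of mature B cells cannot be told apart either. The 8 B cell markers had a median of 0.42 (95% interval of the score difference −0.06 to 1.12), which met the bound chosen against this explanation. But that bound assumed a fixed ratio of B cell markers to immunoglobulin, and 4 of the 8 had the high baseline that could hide a small share. The other 4 were well above background on 2 to 5 of the 6 YFP− arrays. Spib at 1.92 (SE 0.93) and Fcrla at 0.99 were dim in YFP−, well above background on 3 and 2 of its arrays. In YFP+ they were so on 6 and 4 arrays, which goes with B cell RNA there, but neither was called. Cd79a at 0.33 (SE 1.16) and Blk at −0.25 (SE 0.67), on 4 and 5 arrays of each group, were not counted as dim in YFP− and differed little. These 2 are too few, with errors too wide, to decide. The median of the 4 was 0.66. The 95% interval of their score difference, from −0.26 to 1.75, also ends below 1.86, 0.5 of the immunoglobulin score difference.

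Tissue-resident macrophage genes were higher in YFP−. The 16 members chosen as not expressed by fibroblasts, endothelial and epithelial cells had a median of −0.54 (exact permutation p = 0.0022). Among them Timd4, Vsig4 and Cd209f were at −2.16, −1.78 and −1.70. If those cells lack these transcripts, which was not measured here, that argues against RNA of those cells as the whole cause for these members. But they belong to the list that defines the pattern, with 27 of 29 members negative, and were chosen after its values were seen. They are therefore no separate test of the list. Array brightness cannot be told apart from the group, as the whole cause or as 0.5 or more of it, since the coefficient was −0.62 with it as a covariate (95% interval −1.25 to 0.0011, which reaches 0) and −0.60 without, although the list passed camera in that fit (adjusted p = 9.8e-05). Dendritic cell genes were higher in YFP+ (median 0.39, score higher in 6 of 6 tumour numbers, exact permutation p = 0.082), which goes against dendritic cell RNA in the YFP− samples. Neutrophil (−0.40) and mast cell, basophil and eosinophil markers (−1.07) were higher in YFP−, so granulocyte RNA stays open, and platelet RNA was not tested. A difference between the lineages that the design names stays open and was not tested further.

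Few other divisions of the samples matched either count, which met the bound used for each, but chance division is not excluded. The other divisions were drawn without regard to slide, while the real one is balanced over the slides. Of 100 divisions of the 12 arrays into 6 and 6, 2 gave at least the 356 features of the real one, itself included. The highest other gave 1372, which points to a structure of the samples. That division had all 4 arrays of slide 3 on the same side, but 5 others that did so gave 0 or 1, so slide 3 alone does not account for it, and its cause was not found. With slide as a block 556 features were called in the real division. For lists, 3 of 100 gave at least 14, and the highest other gave 15. The others with 14 and 15 were each 1 array per group off the real division, so they keep much of its difference. Of the 99 other divisions 91 called 1 or more lists, with a median of 6, but many keep part of the real difference. Divisions with 3 arrays of each group on each side, which balance the groups, called 0 to 10 lists. So camera with the preset correlation calls lists for other divisions too, and a single list call does not hold at the nominal rate.

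In 31 of 322 groups of 6 arrays 1 array stood apart from the other 5 (9.63%, where chance gives about 1 in 20), most often the YFP− array of tumour 6 with 10 and the YFP+ array of tumour 6 with 4. Values are log2 signals relative to the array's 75th percentile for genes and centred scores for lists. The YFP− array of tumour 6 was lowest in its group for MHC class I genes (−0.37), Aurkb (−6.91), Batf3 (−4.38), H2-DMb2 (2.28), Hspb1 (−2.62), Ifit3 (0.20), Mcpt4 (−2.31), Psmb8 (1.56) and Usp18 (−4.24), and highest for neutrophil markers (0.90). The YFP+ array of tumour 6 was lowest for interferon response genes (−0.72), Adgre1 (3.18) and Ifit3 (−1.16) and highest for Gm3776 (−3.54). Among YFP+ arrays, tumour 2 was highest for inflammatory genes (0.54) and immediate early genes (0.45), tumour 3 highest for Adamts4 (−3.14) and lowest for Amy2a5 (0.35), tumour 1 highest for Ebf1 (−4.30) and F2rl1 (−4.24), tumour 4 lowest for Ccn1 (−4.10) and Mcpt4 (−7.27), and tumour 5 highest for Ms4a4d (−4.28). Among YFP− arrays, tumour 2 was highest for chemokine receptors (0.57), and the lowest were tumour 3 for Cela1 (−3.89), Lox (−2.00) and Oas2 (−0.17), tumour 4 for Fgf1 (−2.09) and Krt8 (1.43), tumour 5 for Adamts4 (−5.25) and tumour 1 for Ccr10 (−5.08).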

How the results depend on the processing

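The fits with array brightness as a covariate, without slide 3 and within each slide were chosen after the data were seen. The collagen and structural matrix, fibroblast and epithelial lists passed under all 16 settings fixed in advance and run for single lists on all 12 arrays. They also passed with every left-out array and the brightness covariate. The other 11 of the 14 called lists lost their call under at least 1 of the settings fixed in advance. Fits without 1 pair are not among the 16, since for lists they gave only counts. Of 49 named genes called, 24 passed in all of the up to 14 such settings run for single genes, which also leave out the fits without 1 pair. With each array left out in turn 37 passed, and 3 (Iglv1, Nid1 and Postn) with the brightness covariate. The other 12 kept their call in 1 (Mmp3), 2 (Adamts4, Lyar, Strc), 3 (Cela1, Hbb-bt), 4 (Cxcl5, Hba-a2, Ltb4r1, Timp3), 7 (Hbb-b1) and 9 (Col1a1) of 12 fits with 1 array left out, with a highest adjusted p from 0.059 (Col1a1) to 0.11 (Cela1). Called features, in all and then higher in YFP+ and in YFP−, were 356, 68 and 288. They became 556, 123 and 433 with slide as a block, 562, 125 and 437 at an adjusted p under 0.10, and 547 with 451 higher in YFP− after normexp. Median centring called 116 higher in YFP+, with 33.5% of calls in that direction against 19.1%. With probes above background on all arrays 233 were called, 40 of them higher in YFP+, and 8 lists, over fewer genes. Lists called fell from 14 to 3 with an estimated correlation and to 8 with fry. With brightness as a covariate, which differs between the groups and so takes up part of the same difference, 13 features (4 and 9) and 8 lists passed. The median standard error of the 356 rose from 0.48 to 0.83 and their median size went from 2.94 to 2.71 on the log2 scale, so most of these calls ended with wider errors. The sign was kept in all 356, which were selected on the same arrays. In the same fit the cell cycle median turned to −0.22, and the B and plasma cell test turned direction with a median of 0.37; the cause was not tested. Without slide 3, with fewer samples, 196 were called (36 and 160) and the acinar, MHC class II, matrix remodelling and neutrophil lists lost their calls. Within slides 1, 2 and 3, with 2 arrays against 2, limma called 0 features in all and 0 in each direction, with 1848, 1796 and 1617 at an unadjusted p under 0.05. Camera called 7, 12 and 11 lists within them. The cell cycle median was −0.22 within slide 3. Leaving out 1 array gave 266 to 383 features, 37 to 86 higher in YFP+, 208 to 297 higher in YFP−, and 9 to 15 lists. The YFP+ count moved by over 1.5 times without the YFP+ arrays of tumours 1 (38), 3 (43), 4 (42) or 5 (37) or the YFP− arrays of tumours 2 (45) or 3 (42), and the list count without the YFP+ array of tumour 4 (9). Of the 12 fits with 1 array left out, the call was kept in 5 for matrix remodelling, 6 for MHC class II, 8 each for cell cycle and for B and plasma cell genes, 10 for neutrophil and 11 for mast cell, basophil and eosinophil genes. The median difference of all genes moved from −0.03 to 0.18 with median centring. Dim spots limit folds where a gene is above background on few arrays of a group.

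Arrays with the same tumour number deviated together with correlations of −0.30, 0.11, −0.13, 0.37, 0.19 and 0.28 across genes, over 0.1 in 4 of 6, and 2 of 6 correlated best with their own number. Pairing was to be taken from correlations over 0.1 in all 6, so the numbers were not taken to pair the samples. The 3 pairs that share a slide, tumours 4, 5 and 6, had 0.37, 0.19 and 0.28. With slide means removed, the correlations of tumours 1 to 6 were 0.077, 0.132, 0.132, −0.239, −0.215 and −0.095. Slide and tumour number are mixed in this check, so it does not show that the samples are unpaired. With the replicate block 296 features (50 and 246) and 14 lists were called, among them 38 of the 68 and 196 of the 288 features called without it, and with block and slide together 201 (33 and 168). Among the named genes, the replicate block alone ended 13 calls and added 5. With the block and 1 tumour number left out, the ranges were 93 to 254 features, 15 to 42 higher in YFP+, 78 to 217 higher in YFP−, and 12 to 14 lists.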

Other observations

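The features in the next sentences were singled out after their values were seen. A cluster of neighbouring features on chromosome 9 fell together in YFP+. Within 78090411 to 78178915 of build mm9 (per the file headers), a span of 88.5 kb, all 4 tested features were called and higher in YFP−: Gm3776 57.1-fold, Gm10639 33.4-fold, Gsta2, a glutathione S-transferase of the alpha class, at least 10.1-fold, since it was not well above background on any YFP+ array, and an unnamed transcript. Gm3776 and Gm10639 were well above background on 1 of 6 YFP+ arrays each. Within 100 kb on either side of the Gm3776 and Gsta2 probes, the other 3 tested genes were Cilk1 (log2 −0.43, limma adjusted p = 0.86), Ddx43 (−0.59, adjusted p = 0.86) and Cgas (−0.05, adjusted p = 0.98), and none passed. Whether the 4 probes detect separate transcripts or share near-identical sequence was not tested.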
